A study of Arabidopsis thaliana with 10 samples.

How the data were processed

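The series holds 10 samples of Arabidopsis thaliana, ecotype Col-0. The 6 used here are chromatin immunoprecipitation (ChIP-seq) libraries from expanded leaves of 3-week-old wild-type plants: 1 input DNA library, 1 ChIP with an antibody against histone H3, and 1 ChIP each with antibodies against H2A, H2A.W, H2A.X and H2A.Z. The other 4 samples, bisulfite and mRNA libraries of wild type and of the hta6 hta7 hta12 mutant, were not analysed here. Per the labels' protocols, leaves were fixed with formaldehyde, nuclei were washed and lysed, chromatin was sonicated, and the immunoprecipitated DNA was made into Illumina libraries.

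Each deposited file is a list of distinct read sequences of 50 bases with the count of reads that had that sequence. The authors collapsed identical reads into such counts, and the deposited values hold no position, strand or base quality. Bowtie is named, without a version or role, per the submitters' processing notes; the genome build is not given in the sources used here. The counts were used as deposited, with no filter.

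No genome sequence was used here, so reads could not be placed on chromosomes or annotated genes. The planned comparisons of pericentromeres with chromosome arms, of transposable elements (TEs) by arm and by length, and the planned lists of named genes were therefore not run. The approach below was chosen after the files had been seen. Contigs were built from the pooled reads of all 6 libraries as unbranched paths of 25-base words present in at least 3 distinct read sequences and, where paths branch, in at least 5% of the number of the most frequent branch, with a C++ program compiled with g++ 11.4.0. This gave 486055 contigs, 119 Mb in all, with an N50 of 1035 bp. Each read was assigned to the contig that held its leftmost 25-base word. Before that step, reads of the centromere satellite, the 5S and 45S ribosomal DNA (rDNA) and the telomere repeat were set aside by their 15-base words shared with short reference sequences of these repeats, written from general knowledge. At least 5 shared words were needed for the satellite and 5S rDNA, 12 for 45S rDNA and 25 for the telomere repeat.

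The copy number of a contig was its input depth over the median input depth of contigs of 1000 bp or more. Contigs with a copy number of 8 or more and log2(input/H3) of 0.75 or more were called organelle DNA, with chloroplast contigs at 3.5 or more. The remaining organelle contigs were taken as mitochondrial. They were split at 2.1 into contigs called mitochondrial-only and contigs called mitochondrial and nuclear. These names rest on read depth alone, since no organelle or nuclear genome sequence was compared. These limits were set at gaps in the distribution after it had been seen. Contigs between 0.5 and 1.7 copies were called single-copy.

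TE and gene-family loci were found by matching protein sequences, also written from general knowledge, to contigs of 200 bp or more with tblastn 2.17.0 at an E-value of 1e-05. Matches within 1 kb were merged, extended by 250 bp on each side, and kept at 500 bp or more with at least 50 H3 reads. A locus belongs to the family of its best match, and the median amino-acid identity of a family's matches ranged from 30.2% to 94.1%. Families with fewer than 5 loci were left out. Open reading frames (ORFs) from ATG to stop of at least 600 bp on single-copy contigs without a TE match stood in for genes in the profiles. They can miss the true start of a gene where an exon begins upstream.

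Enrichment was log2 of ChIP over H3, each divided by the library's nuclear reads, which exclude organelle contigs and reads without a contig. Loci and windows had a pseudocount of 1 read added after scaling to the H3 depth. With 1 library per group there was no test and no p-value. Intervals for sums of reads are exact Clopper-Pearson 95% intervals, and those for medians are bootstrap intervals over loci from 2000 draws. Both cover only counting error or the spread over loci within these libraries, since amplified reads are not independent molecules and no library was repeated. A family median was placed among the medians of 10000 random lists of other gene loci and ORFs matched on length and H3 reads. The length of a locus includes its flanks of 250 bp, while ORFs have none, so the lists are not matched on flanking sequence. Profiles used reads shifted by 75 bp towards the fragment centre, in 50-bp bins. Windows of 1 kb had at least 20 H3 reads. Correlations over windows were set beside 50 simulations of unchanged libraries sharing one H3 library. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1.

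The calculations were tested on simulated counts. Of 100 windows raised 4-fold among 49188 windows, 100% passed the log2 threshold of 1 in each of the 4 simulated comparisons, while of 100 raised 2-fold, which lie at the threshold, 44% to 48% did. For a simulated 2-fold difference between TE and gene-family loci over 1882 loci, the recovered log2 difference was 1.00 for H2A, 1.00 for H2A.W, 1.01 for H2A.X and 0.97 for H2A.Z. The interval of the last, 0.95 to 1.00, ended just under the true value.

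The rule fixed in advance for named genes took the genes and TEs with the highest and lowest enrichment, the extremes of each gene list, and FLC, ACT2, UBQ10 and RBCS1A. It needs annotated genes, so of these only FLC, found by a match at 100% identity, is reported. Alternatives were input as the denominator, distinct sequences counted once, other minimum read numbers, pseudocounts, shifts and thresholds, thinned libraries and GC matching. Scaling to single-copy contigs of 500 bp or more, contigs built from 29-base words, 2-kb windows, other ORF sets and summed profiles were added after the data had been seen.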

Results

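The 4 H2A types of Arabidopsis leaf chromatin were compared by ChIP-seq in wild-type plants, each with 1 library, beside 1 H3 ChIP library as the measure of nucleosome level and 1 input library. H2A.X and H2A.Z are histone variants found across eukaryotes, and H2A.W is a plant variant with an extended C-terminal tail. The libraries held 25859277 reads (input), 29106632 (H3), 26510823 (H2A), 15524753 (H2A.W), 30342020 (H2A.X) and 17691505 (H2A.Z). Between 56.0% (input) and 77.6% (H2A.Z) of the reads were assigned to nuclear sequence. Distinct sequences made up 79.4% of the H2A.W reads and 96.8% of the H2A.Z reads. No group had a replicate, so the comparisons are between libraries and none has a test. All intervals are 95% intervals.

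The first comparison asked how the H2A types are spread over the repeats of the nuclear genome. H2A.W was higher than H3 on each of the 4 repeat classes, while H2A.Z was lower on each. On the centromere satellite, the tandem repeat of Arabidopsis centromeres, log2(H2A.W/H3) was 1.23 (1.23 to 1.24), a 2.35-fold excess, and log2(H2A.Z/H3) was -2.07 (-2.07 to -2.06). The satellite took 27.1% of the nuclear H2A.W reads, against 11.5% of those of H3, 8.69% of those of input and 2.75% of those of H2A.Z. Over H3, H2A.W was close to this level on the genes of the structural RNAs of the ribosome, at 1.25 (1.24 to 1.27) on 5S rDNA and 1.27 (1.26 to 1.28) on 45S rDNA. H2A.Z on them was at -2.21 (-2.24 to -2.18) and -1.87 (-1.88 to -1.85). Over input, H2A.W was at 1.64 on the satellite and at 2.02 on both 5S and 45S rDNA, and H2A.Z at -1.66, -1.44 and -1.12.

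H2A and H2A.X were between these extremes. H2A was at -0.87 (-0.88 to -0.87) on the satellite, -1.44 (-1.46 to -1.42) on 5S rDNA and -0.42 (-0.43 to -0.41) on 45S rDNA. H2A.X was at -0.35 (-0.36 to -0.35) on the satellite, -0.83 (-0.84 to -0.81) on 5S rDNA and -0.03 (-0.03 to -0.02) on 45S rDNA. Over input in place of H3, the direction changed for H2A.X on the satellite, at 0.05 (0.05 to 0.06), and for both types on 45S rDNA, at 0.33 for H2A and 0.72 for H2A.X. H2A on the satellite was then at -0.47, and on 5S rDNA H2A was at -0.67 and H2A.X at -0.056. Telomere repeats rested on far fewer reads, 1091 for H2A.W and 174 for H2A.Z. There log2(H2A.W/H3) was 0.52 (0.40 to 0.63), log2(H2A.X/H3) was 0.46 (0.36 to 0.55), log2(H2A/H3) was -1.05 (-1.18 to -0.92) and log2(H2A.Z/H3) was -2.64 (-2.87 to -2.41). Against input, the telomere value of H2A.W was 0.02 (-0.09 to 0.13) and that of H2A.X was -0.04 (-0.13 to 0.05).

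**Figure D1:**
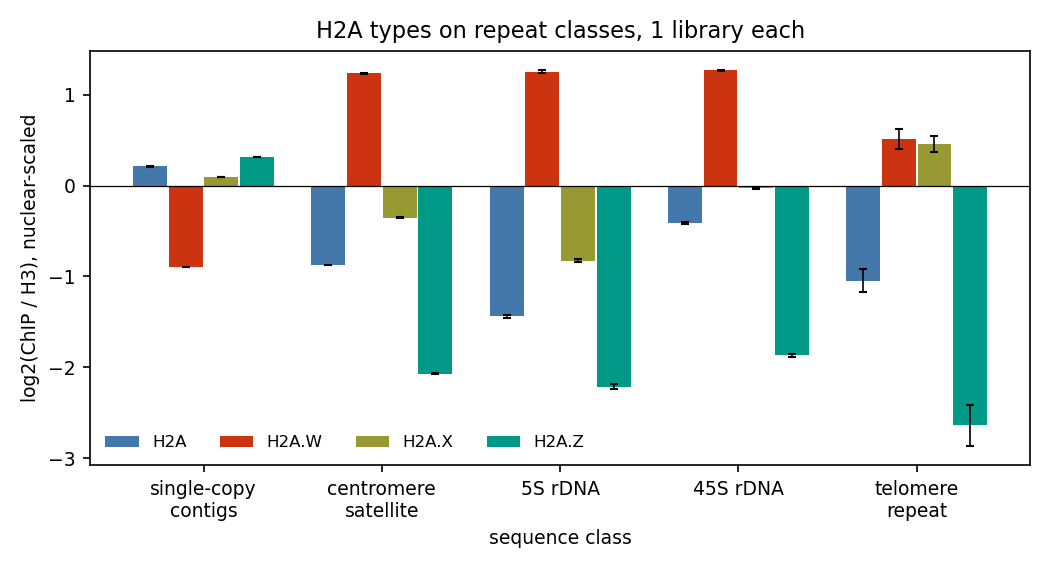
Log2 of ChIP over H3 reads, each scaled to nuclear reads, for the 4 H2A types on single-copy contigs and 4 repeat classes; bars are 1 library each and whiskers are exact intervals for counting error. H2A.W lies above 0 on the 4 repeat classes and at -0.89 on single-copy contigs, and H2A.Z lies at -1.87 or below on the repeats.

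Single-copy contigs of 100 bp or more, 98.6 Mb in all, held 38.0% of the nuclear H2A.W reads, against 70.5% of those of H3 and 87.9% of those of H2A.Z. Because the repeats took so much of the H2A.W library, the choice of scaling sets where 0 lies. Scaling to the reads on single-copy contigs of 500 bp or more, a part of this class, moved every H2A.W value by 1.14 on the log2 scale, and those of H2A by -0.29, of H2A.X by -0.13 and of H2A.Z by -0.34. With it, H2A.W on the satellite was 2.38 and H2A.Z -2.41. Differences between loci within a library do not depend on this choice, apart from the pseudocount.

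The second comparison set TEs against loci of selected protein-coding gene families. Over 398 loci that matched TE proteins, the median log2(H2A.W/H3) was 1.16 (quartiles 0.39 to 1.36), and over 1484 gene-family loci it was -1.73 (quartiles -2.13 to -1.36). The difference was 2.90 (2.85 to 2.94), 7.45-fold. H2A.Z went the other way, with a TE median of -1.63, a gene median of 0.52 and a difference of -2.15 (-2.23 to -2.06). The difference for H2A was -1.14 (-1.21 to -1.07) over H3 and -0.75 (-0.82 to -0.68) over input. H2A.W was above H3 at 77.4% of the TE loci and at 1.55% of the gene loci. Receptor-like kinases, with 543 loci, and pentatricopeptide repeat proteins, with 380, weigh most in the gene medians. With long ORFs in place of the gene families the differences were -1.36 for H2A, 2.93 for H2A.W and -1.94 for H2A.Z. Of the TE loci, 397 lay on contigs at single-copy depth, so the values are mostly those of diverged copies.

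For H2A.X the outcome depended on the denominator. The TE minus gene difference was -0.34 (-0.41 to -0.28) over H3 and 0.01 (-0.04 to 0.07) over input, and it was -0.60 over H3 at loci with at least 200 H3 reads. H3 itself was higher on TEs than on genes relative to input, by 0.36 (0.32 to 0.39).

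H2A.W was above 0 in the median of each of the 7 TE families and below 0 in each of the 19 gene families, under both scalings. The TE families comprise retrotransposons, which copy through RNA, and DNA transposons. The highest medians were those of Ty3/gypsy elements, 1.36 (1.26 to 1.39) over 28 loci, and of the Athila type of that group, 1.35 (1.12 to 1.51) over 10 loci. LINE elements had a median of 1.24 (1.19 to 1.29) over 166 loci, and Ty1/copia elements 1.08 (0.98 to 1.14) over 128. hAT transposases, a family of DNA transposons, had the lowest TE median, 0.31, with an interval of -1.26 to 0.81 over 23 loci. The interval of MULE transposases also reached below 0, at -0.05 to 1.22 over 36 loci. H2A.Z was below 0 in the medians of the same 7 families, from -0.90 for hAT to -2.02 for Athila.

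**Figure D2:**
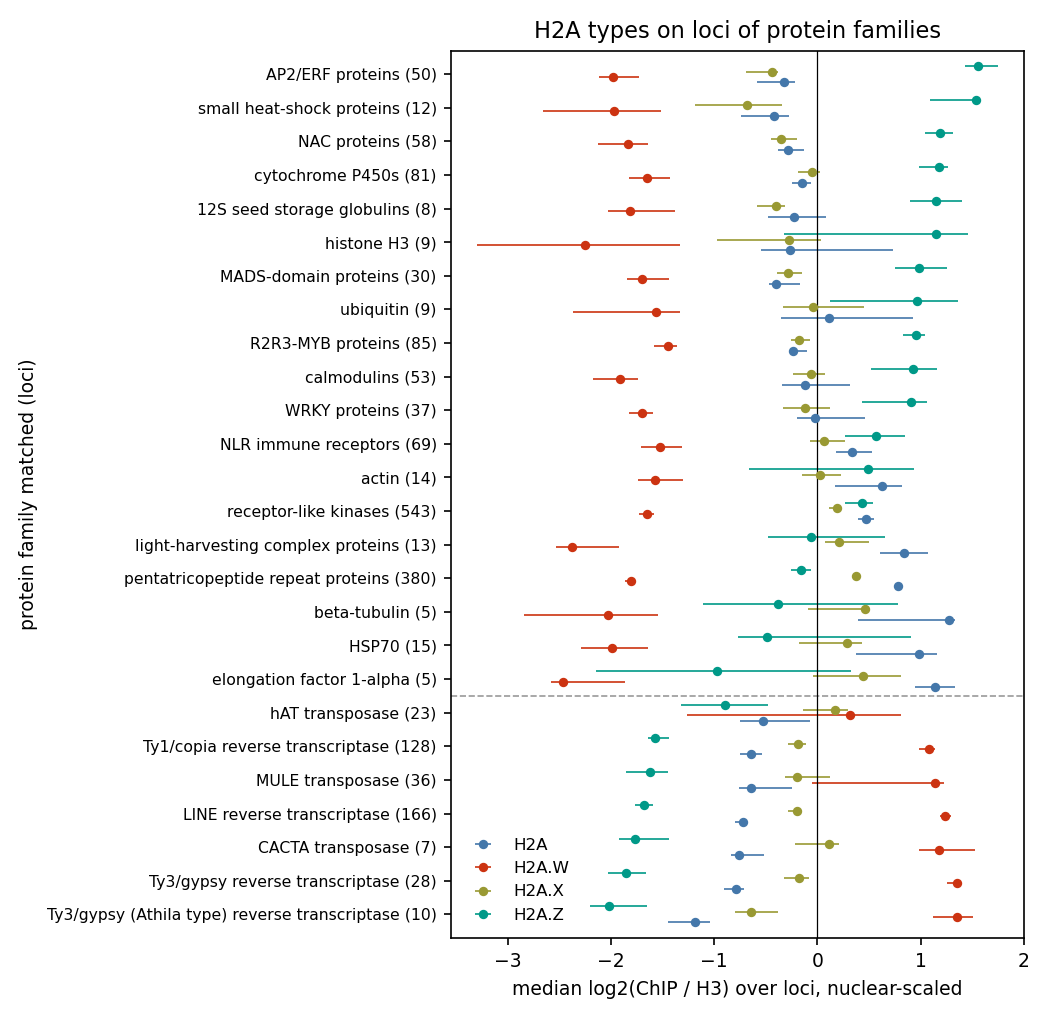
Median log2 of ChIP over H3 for each protein family (number of loci in brackets), with gene families above the dashed line and TE families under it; points are medians of 1 library and lines are bootstrap intervals over loci. H2A.W lies at 0.31 or above in the TE families and at -1.45 or below in the gene families.

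Among the gene families, H2A.Z varied most, from a median of -0.97 to one of 1.55. The lowest was that of elongation factor 1-alpha, with an interval of -2.14 to 0.32 over 5 loci and a median identity of 30.2%. AP2/ERF proteins, transcription factors that include regulators of cold and ethylene responses, had a median log2(H2A.Z/H3) of 1.55 (1.43 to 1.75) over 50 loci, above all 10000 random lists. Small heat-shock proteins, chaperones induced by heat, were at 1.53 (1.09 to 1.59) over 12 loci, percentile 99.7. HSP70, another heat-shock family, had a median below 0, at -0.49 (-0.77 to 0.91) over 15 loci, percentile 15.5. Loci matching NAC transcription factors were at 1.19 (1.04 to 1.31) over 58 loci, percentile 99.7, and cytochrome P450s, enzymes of secondary metabolism among others, at 1.18 (0.99 to 1.26) over 81 loci, percentile 99.9. Pentatricopeptide repeat proteins, which act on organelle RNAs, were at -0.16 (-0.26 to -0.06) over 380 loci, percentile 0.42. This value was -0.028 over input, -0.36 at loci with at least 200 H3 reads and -0.50 with single-copy scaling. Loci matching light-harvesting proteins, which bind chlorophyll in the chloroplast, were at -0.06 (-0.48 to 0.66) over 13 loci, percentile 1.95. The median amino-acid identity of the matches was low for several of these families, at 38.3% for pentatricopeptide repeat proteins and 41.1% for light-harvesting proteins, with small heat-shock proteins between them. These families were chosen after the files had been seen.

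The median of H2A was -0.33 (-0.59 to -0.22) for AP2/ERF proteins, -0.28 (-0.38 to -0.13) for NAC proteins and -0.15 (-0.24 to -0.06) for P450s, each under all 10000 random lists, and -0.42 (-0.74 to -0.27) for small heat-shock proteins, percentile 0.12. Over input it was -0.18 for AP2/ERF proteins and -0.041 for P450s. Low H2A was not particular to these families, since 10 of the 19 gene families lay at or below percentile 2.5 of their random lists. It was 0.78 (0.75 to 0.82) for pentatricopeptide repeat proteins and 0.84 (0.61 to 1.07) for light-harvesting proteins, within their random lists at percentiles 94.7 and 89.2. Under single-copy scaling these 6 H2A medians kept their sign, while that of ubiquitin changed from above to below 0. The NLR immune receptors, whose matches had a median identity of 34.0%, lay close to their random lists for H2A.Z, at 0.56 over 69 loci and percentile 68.6. Loci matching 12S seed storage globulins, proteins of the seed, were at 1.15 (0.90 to 1.40) for H2A.Z over 8 loci, percentile 95.8, and at -0.22 (-0.48 to 0.08) for H2A, percentile 1.78.

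FLC (AT5G10140), a repressor of flowering, was named in advance. Its first coding exon was found in a 533-bp locus with 92 H3 reads. The log2(H2A.Z/H3) there was 1.44 (1.06 to 1.82), from 167 H2A.Z reads, while H2A was at -0.64 (-1.15 to -0.14), H2A.X at -1.19 (-1.74 to -0.65) and H2A.W at -1.86 (-2.86 to -0.99), the last from 12 reads. Its chromosomal position is not given, since the contigs were not placed on a genome.

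The third comparison followed the H2A types along genes, with 5622 long ORFs in their place. H2A.Z was highest 50 to 100 bp after the start, at a mean log2(H2A.Z/H3) of 0.35, and averaged -0.17 from 500 to 1000 bp after it. The rise was 0.51 (0.48 to 0.54). In ORFs under 1 kb this stretch reaches past the stop, for each H2A type. Over ORFs of 1 kb or more the H2A.Z rise was 0.64. Counted from the stop, H2A.Z was at -0.40 at 150 to 200 bp past it. H2A and H2A.X had no such peak: H2A went from 0.23 at the start to 0.49 at 950 to 1000 bp, and H2A.X from -0.05 to 0.26. H2A.W stayed between -1.69 and -1.56 over the 2 kb around the start.

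**Figure D3:**
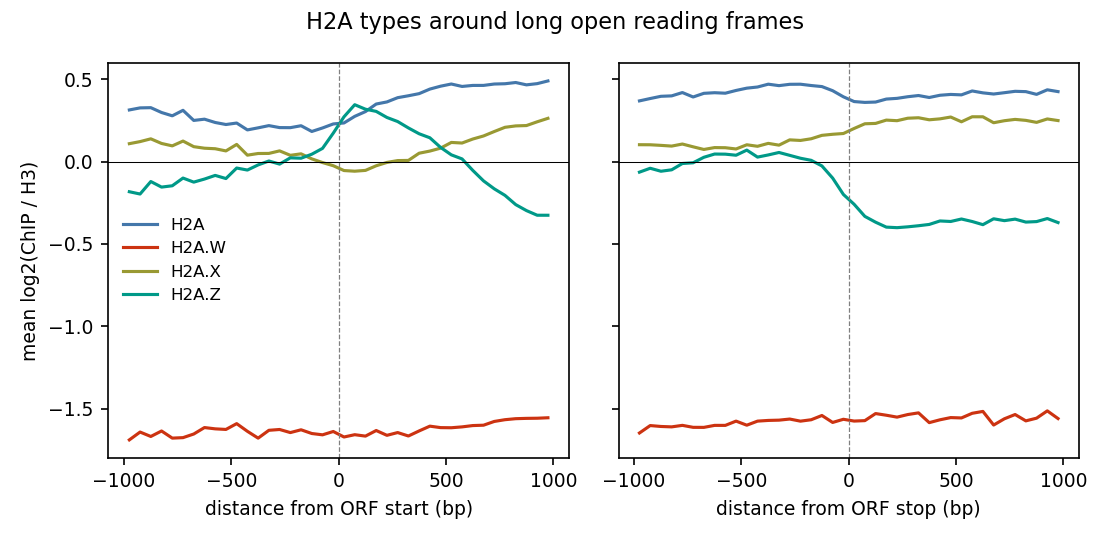
Mean log2 of ChIP over H3 in 50-bp bins from 1000 bp before to 1000 bp after the start (left) and the stop (right) of 5622 ORFs; each line is 1 library, and bins farther out rest on fewer ORFs. H2A.Z peaks at 0.35 just after the start and lies at -0.40 past the stop.

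H2A.Z was lower over longer ORFs. Its median fell from 0.77 (0.63 to 0.88) in the shortest of 5 equal groups, of 600 to 669 bp, to -0.12 (-0.22 to -0.05) in the longest group, of 1308 bp and more. H2A rose from 0.34 (0.26 to 0.45) to 0.84 (0.80 to 0.86) over the same groups, and H2A.X from 0.04 (-0.03 to 0.09) to 0.37 (0.34 to 0.39). H2A.W was at -1.75 and -1.76 in the shortest and the longest group.

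The last comparison asked which H2A types share regions, over 49188 windows of 1 kb. These windows lie mostly in the single-copy part of the genome and are not independent replicates. H2A and H2A.X went together, with Pearson's r of 0.76 and Spearman's rho of 0.78. H2A.Z went against both, with r of -0.48 (rho -0.52) for H2A and r of -0.62 (rho -0.68) for H2A.X. H2A.W and H2A.Z had r of -0.21 and rho of -0.08, and the r of this pair was -0.10 over 2-kb windows and -0.14 over input. H2A and H2A.W had r of -0.43 (rho -0.35) over H3 and -0.087 over input. The r of H2A.W and H2A.X changed sign, from -0.093 over H3 to 0.27 over input. Unchanged libraries sharing the H3 reads gave r from 0.36 to 0.50 in simulation. The covariance of H2A and H2A.X was 0.20, against 0.01 in simulation, and that of H2A.X and H2A.Z was -0.25, against 0.01. With the H3 reads split at random in 2, with 1 part for each type, r was 0.67 for H2A and H2A.X and -0.62 for H2A.X and H2A.Z.

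At a log2 threshold of 1, H2A.W was enriched in 1376 windows, 2.80% (2.65 to 2.95), H2A.Z in 8407, 17.1% (16.8 to 17.4), H2A in 7440 (14.8% to 15.4%), and H2A.X in 22. No window was enriched in both H2A.W and H2A.Z, where independent lists of these sizes would share 235, or in both H2A.W and H2A, where they would share 208. H2A and H2A.Z shared 11 windows, against 1272 for independent lists. Inside the H2A.W-enriched windows the median of H2A.Z was -1.85, against 0.25 outside, and that of H2A was -0.93, against 0.28. These shares depend on the scaling: with single-copy scaling they were 4.70% for H2A.W, 6.68% for H2A.Z and 2.13% for H2A, and at a log2 threshold of 0.58 the shares were 35.2% for H2A.Z, 38.8% for H2A and 11.3% for H2A.X.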

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

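The tests in this part were chosen after the result was seen. Organelle DNA enters none of the comparisons above, and 6 values in it stood above the H3 library, whose level served as control. On chloroplast contigs the log2 ratio to H3 was above 0 in the 4 H2A types, at 2.00 (1.98 to 2.02) for H2A, 0.90 (0.88 to 0.92) for H2A.W, 0.70 (0.68 to 0.72) for H2A.X and 0.80 (0.78 to 0.82) for H2A.Z. For H2A.W it was also 1.54 (1.52 to 1.56) on mitochondrial-only contigs. It was 1.55 (1.54 to 1.57) on contigs called mitochondrial and nuclear, both classes being named from read depth alone. The other types were below H3 on both, in the same order at -0.31 and -0.66 for H2A, -0.28 and -0.36 for H2A.X, and -1.33 and -1.71 for H2A.Z.

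Mitochondrial-only contigs, 219 kb in all, had 14.0 times the depth of single-copy contigs in input, 1.46 times in H3 and 9.36 times in the H2A.W library. In these units, chloroplast contigs kept 2.55% of their input depth in the H2A.W library and mitochondrial-only contigs 67.0%. The units raise the H2A.W values, since H2A.W was at -0.89 over H3 on single-copy contigs. Scaled to nuclear reads, log2(H2A.W/input) was -6.51 on chloroplast contigs and -1.80 on mitochondrial-only contigs. The ratio between the shares of the organelles does not depend on the units. If input DNA had been carried through the immunoprecipitation unchanged, both organelles would keep the same share of their input depth. Instead, the chloroplast share was the lower in each ChIP library. Its ratio to the mitochondrial share was 0.038 for H2A.W, 0.059 for H3, 0.12 for H2A.X, 0.26 for H2A.Z and 0.29 for H2A. The H2A.W ratio was 0.64 (0.63 to 0.65) times that of H3, the nearest library. That comparison decides nothing, since limits on input over H3 (chloroplast at log2 of 3.5 or more) separate these contigs and lower the H3 ratio. Within the H2A.W library, carry-over alike for both organelles would leave mitochondrial-only contigs no more than 2.55%, and so does not account for 67.0%. Carry-over that favours mitochondrial DNA was not tested and stays open. Another candidate explanation is that copies of mitochondrial DNA lie in nuclear heterochromatin, as is known for a large insertion in Arabidopsis. This stays open too. With a chloroplast-based carry-over of 0.087 taken off, the H3 depth of mitochondrial-only contigs was 1.37 (1.36 to 1.38) single-copy units, but the limits on input over H3 that define these contigs already require at least 0.82, so this depth decides nothing. Losses that differ between the organelles before the immunoprecipitation were not tested. They would cancel in shares of input depth if the input came from the same chromatin as the ChIP libraries. No biological contrast of the design bears on the mitochondrial sequence in the H2A.W library.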

How the results depend on the processing

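Scaling to single-copy contigs, 29-base words, 2-kb windows, long ORFs as the comparison, ORFs of 1 kb or more and summed profiles were chosen after seeing the data. No paired analysis was possible because each group had 1 library. For 47 signed values with an interval that excludes 0, alternatives gave 269 further values, and 263 of these had the same sign. Some alternatives can hardly change a sign, such as single-copy scaling for differences and correlations. Over input, 41 of 47 values kept their sign. The 6 exceptions were all over input: the satellite, telomere and 45S rDNA values of H2A.X at 0.053, -0.038 and 0.72, the 45S rDNA value of H2A at 0.33, the H2A.X difference between TEs and gene families at 0.012, and the r of H2A.W and H2A.X at 0.27. Over input, each repeat value moves by definition by the log2(H3/input) of its class. This was 0.41 on the satellite, 0.77 on 5S rDNA, 0.75 on 45S rDNA and -0.49 on telomere repeats. Apart from this and the scaling, which moves 0, the cause was not tested for the changes below.

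Over input, H2A.W and H2A.Z on the satellite were 1.64 and -1.66, and the TE minus gene differences of H2A, H2A.W and H2A.Z were -0.75, 3.26 and -1.66. With distinct sequences the satellite values were 1.41 and -1.73, with single-copy scaling 2.38 and -2.41, and with 29-base words 1.17 and -2.03. Words of 29 bases gave an H2A.Z difference of -2.23. At least 200 H3 reads gave differences of -1.59 for H2A, -0.60 for H2A.X and -1.70 for H2A.Z. A pseudocount of 5 gave 2.79 for H2A.W and -2.06 for H2A.Z, GC matching gave -2.04 for H2A.Z, and long ORFs as the comparison gave -1.36 for H2A and -1.94 for H2A.Z. The H2A.Z rise at ORF starts was 0.45 without the shift, 0.55 from summed reads and 0.64 over ORFs of 1 kb or more.

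For H2A with H2A.W, r was -0.087 over input, -0.51 over 2-kb windows, -0.48 with 29-base words and -0.45 with H3 split in 2. For H2A with H2A.X it was 0.82, 0.83, 0.79 and 0.67 in the same order, and for H2A.W with H2A.Z -0.14, -0.10, -0.19 and -0.22. For H2A.W with H2A.X the last 3 were -0.24, -0.15 and -0.14. For H2A with H2A.Z r was -0.44 over input, -0.56 over 2-kb windows and -0.49 with H3 split, and for H2A.X with H2A.Z -0.55 over input, -0.67 over 2-kb windows and -0.61 with 29-base words.

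The shares of enriched windows for H2A.W and H2A.Z, 2.80% and 17.1%, were 3.19% and 15.2% over input, 3.24% and 12.8% with distinct sequences, 3.52% and 35.2% at a threshold of 0.58, 4.70% and 6.68% with single-copy scaling, and 3.20% and 18.3% with 29-base words. Thinning gave 17.5% for H2A.Z. The H2A share was 38.8% at a threshold of 0.58 and 2.13% with single-copy scaling. The H2A.X share, 0.045%, was 1.22% over input, 11.3% at 0.58, 0.57% after thinning, 0.086% with 29-base words, 0.018% with distinct sequences and 0.0020% with single-copy scaling.

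Alternatives that need chromosome positions were not run, namely other pericentromere widths, chromosome arms alone, arm TEs, wider bins and bins without reads, nor was the start region of listed genes. The H2A.Z median of pentatricopeptide repeat proteins ranged from -0.50 with single-copy scaling to -0.028 over input. Families with fewer than 5 loci of at least 200 H3 reads gave no value at that minimum. Depth limits the telomere and FLC values, which rest on as few as 174 and 12 reads, and without replicates no value has an error between samples.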

Other observations

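The tests of GC content, identical reads, H3 level and CpG named in this part were chosen before their results were seen. The correlations with base composition were chosen after the files had been seen. Base composition set the H2A types apart over the 49188 windows. Spearman's rho with the ratio of observed to expected CpG was -0.50 for H2A, -0.47 for H2A.X and 0.49 for H2A.Z, and 0.01 for H2A.W. With GC content rho was 0.49 for H2A, 0.16 for H2A.X, -0.08 for H2A.Z and -0.24 for H2A.W. These are correlations across windows of 1 library each, and windows are not independent replicates. The negative rho of H2A.W with GC content did not hold for its enriched windows. The 1376 H2A.W-enriched windows had a mean GC content of 40.2%, against 36.7% for the other windows. Most windows were low in H2A.W, with a median log2(H2A.W/H3) of -1.68 over all windows.

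One hypothesis was that H2A.W marks methylated DNA, in which CpG is lost over time. The 1376 H2A.W-enriched windows had a mean observed over expected CpG of 0.63, against 0.70 for other windows matched on GC content, a difference of -0.063 (-0.075 to -0.051). Without matching the gap was smaller, with means of 0.635 and 0.677 and medians of 0.625 and 0.641. The direction is consistent with the hypothesis, but methylation itself was not analysed here, and the rho of 0.01 over all windows was not matched on GC content.

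The excess of H2A.W on TE loci over gene-family loci was weighed against 2 technical explanations. Within groups of equal GC content the difference was 2.85 (2.61 to 2.91), and with each distinct sequence counted once it was 2.88 (2.82 to 2.92), against 2.90. Both values argue against GC content or amplified identical reads as the cause. A difference in how the antibodies perform remains open, since each type has 1 library.

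The rise of H2A.Z at ORF starts was weighed in the same way. If low H3 at starts were the cause, the rise would shrink over input, where it was 0.54 (0.51 to 0.57) against 0.51 over H3. In windows of 200 bp more than 500 bp from any start, with the GC content of the start windows, the change from the level 500 to 1000 bp downstream was -0.074 (-0.087 to -0.060), against 0.46 at the starts. Neither low H3 nor GC content accounts for the rise in these libraries. That H2A.Z sits at gene starts stays a hypothesis here, since ORF starts only stand in for annotated gene starts.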
